A study of Mus musculus with 12 samples.

How the data were processed

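RNA from whole mouse corneas was measured on Affymetrix arrays, with 12 arrays and 45101 probe sets per array. Per the labels' protocols, RNA was extracted with RNeasy columns and 100 ng of total RNA was made into biotin-labelled cRNA by the standard Affymetrix procedure. The deposited values are linear probe-set signals of unit intensity, which the authors scaled on each array to a common level, seen here as a mean of 100 after trimming 2% at each end. The software that made the signals is not given in the sources used here. The arrays are not quantile normalized. Strain is given in the labels, while sex and age are not given in the sources used here.

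Samples were grouped by the genotype, treatment and day in the labels, with no sample moved for its values. Gene symbols came from the platform table. Of the probe sets, 34958 carry 1 symbol, 932 carry several and 9211 carry none, and only those with 1 symbol were used. Of these, 204 have a symbol that is absent from the RefSeq gene table (GRCm38.p6), which served for names and neighbouring genes only. The brightest probe set stood for each of 18194 genes. Genes both named and called gave 478 entries, with a gene entered once for each comparison. Of these entries, 184 have several probe sets, and 10 have at least 1 that moved the opposite way.

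Values were transformed as log2(intensity + 3.6), where 3.6 is the 20th percentile of all values. Genes were tested where they had a mean log2 value at or above the 40th percentile of all probe sets, which left 12711, and Rcan1 and Apoe were kept whatever their level. Differences between intact groups were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per genotype group, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment at 0.05 within each comparison. Comparisons were the 5 pairwise ones, the averages of Dscr1 loss and of Apoe loss, their interaction, and suturing with Dscr1 genotype as a term in 7 arrays. Genotypes with 1 sutured array, and days 7 and 5, were compared as log2 differences without a test, next to 10000 random gene lists matched in expression. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.

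Gene lists were fixed before the data were examined, 35 in number, of which 34 had at least 3 members tested. They were tested with camera at a preset correlation of 0.01 and again with a correlation estimated from the residuals. Genes named in the text were chosen by a rule. Rcan1 and Apoe are given in every sample. Each tested comparison names the 10 largest rises and 10 largest falls past the threshold whose groups do not overlap, or the 5 lowest p where under 5 pass. Each list described names up to 4 members with the largest changes past the threshold, or up to 2 with the lowest p. Single-array comparisons name the 10 highest and 10 lowest differences among genes above the 60th percentile, with up to 4 members of each list.

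The fit was tested on simulated data, with shifts added to 50 genes of each size. For Dscr1KO against WT it found 0% of shifts of 0.5, 10% of 1, 58% of 2 and 100% of 4 on the log2 scale, and for the Dscr1 average 6%, 52%, 90% and 98%. False calls made up between 0% and 6.2% of the calls. The simulated genes varied independently of each other and equally on all arrays. Real replicates differed unequally, at 2-fold in 214 genes in WT and 1638 in Dscr1KO, so these rates need not hold for the data. Alternatives were the stricter filter at the 60th percentile (9867 genes) and no filter, quantile normalization, and pseudocounts of 0.6 and 10.2. Others were no intensity trend, only the groups compared, a replicate block, every probe set tested by itself, and each array left out in turn. Suturing was also fitted on the WT arrays only. Added after results were seen were the intact comparisons without both libraries of doubtful Apoe level, a term for Xist, and the 5 intact arrays with Xist alone. A fit of suturing by genotype was added then as well.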

Results

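Gene expression was measured in whole mouse corneas on 12 Affymetrix arrays, 1 array per sample. The 8 intact corneal samples fall into 4 genotypes of 2 samples each, which the labels call biological replicates. They are C57BL/6J wild type (WT), Dscr1-null (Dscr1KO), Apoe-null (ApoeKO) and null for both genes (double KO). The other 4 samples are sutured corneas, 1 array each: WT at day 5, Dscr1KO at day 5, WT at day 7 and Dscr1 transgenic (Tg) at day 7. Dscr1 is the older name of Rcan1, which encodes a regulator of the phosphatase calcineurin, and Apoe encodes an apolipoprotein that carries cholesterol. Array medians lay between 15.6 and 21.1 intensity units after scaling to a trimmed mean of 100. With 2 arrays per intact group, the number of arrays limits the precision. In the intact comparisons, a p-value weighs a difference against a spread between these samples that is shared over the 4 groups. Adjusted p-values of genes are from limma with Benjamini-Hochberg adjustment over 12711 genes. Those of gene lists are from camera, adjusted over 34 lists, and counts adjusted over the list alone use only its members. Changes are on the log2 scale with their standard errors (SE).

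The transcripts of the targeted genes were read first in every sample. The probe set used for Rcan1 read 630.4 and 649.5 in intact WT, 668.2 and 581.3 in ApoeKO, 477.5 and 335.9 in Dscr1KO, and 379.6 and 331.7 in double KO. Sutured corneas read 663.6 in WT at day 5, 479.1 in Dscr1KO at day 5, 579.7 in WT at day 7 and 548.3 in Tg at day 7. A dimmer Rcan1 probe set read 30.4 and 35.2 in intact WT, 32.7 and 18.5 in ApoeKO, 13.3 and 10.5 in Dscr1KO, and 20 and 12.8 in double KO. In sutured corneas it read 40.6 in WT and 13.1 in Dscr1KO at day 5, and 66.7 in Tg against 53.4 in WT at day 7. Where these probe sets lie relative to the deleted part is not given in the sources used here, so a remaining signal does not test the Dscr1 labels. Apoe read 1030.5 and 776.5 in intact WT and 32.5 and 22.7 in double KO. The library labelled ApoeKO replicate 1 read 849.3, against 7.5 in the library labelled ApoeKO replicate 2. Apoc1, the neighbour of Apoe, read 327.8 and 3.5 in these libraries. Dscr1KO read 1272 and 316.8 for Apoe, and the labels of its replicate 2 name both genotypes, Dscr-1-/- in the title and genotype and ApoE-/- in the source. The group names of the labels were kept for all comparisons, and each count of the intact comparisons was also computed without the library labelled ApoeKO replicate 1 and the library labelled Dscr1KO replicate 2.

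**Figure D1:**
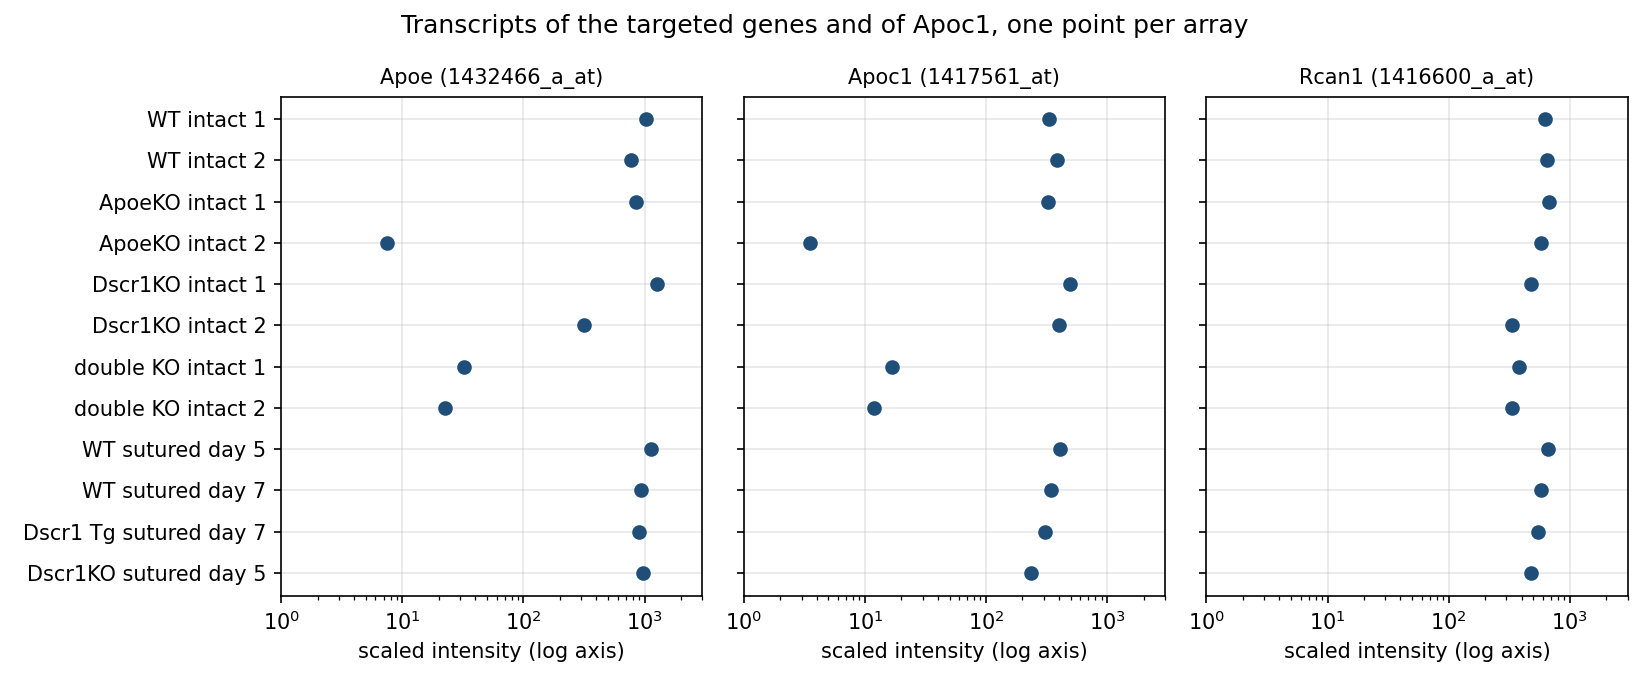
Scaled intensity (log axis) of Apoe, Apoc1 and Rcan1 on each of the 12 arrays, 1 point per array. The library labelled ApoeKO replicate 1 sits at 849.3 for Apoe, with the wild-type arrays, while the library labelled ApoeKO replicate 2 sits at 7.5.

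Sex-linked transcripts divided the intact groups unevenly. Xist, the RNA of the inactive X chromosome, read between 4104 and 5385.2 in both ApoeKO libraries, both Dscr1KO libraries and double KO replicate 1. It read 19.6 or less in WT, double KO replicate 2 and all 4 sutured corneas, in which the Y-linked genes Eif2s3y, Kdm5d and Uty were present. Sex-linked expression therefore divides ApoeKO and Dscr1KO from WT completely. On the first principal component, which held 53.79% of the variance, the 4 intact corneas without Dscr1 lay between 38.21 and 72.69. The other 4 intact corneas lay between -60.62 and -42.32, and the sutured corneas between -14.06 and -1.54.

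The comparison of Dscr1KO with WT asked what loss of Dscr1 changes in the intact cornea. Genes of cornified, skin-type epithelium were near background in WT and bright in Dscr1KO. Krtdap, a gene of differentiating keratinocytes, rose by 9.04 ± 0.68 (adjusted p = 0.000452), from a mean of 4 ± 4.95 to 4574 ± 4069 (SD, n = 2). Klk13, a kallikrein protease, rose by 8.93, the cornified-envelope genes Sprr3, Sprr2f and Sprr2d by 8.61, 8.32 and 8.31, the envelope gene Rptn by 8.11 and Dmkn by 8.05. Mmp13, a collagenase, rose by 7.99 and S100a8, a subunit of the neutrophil protein calprotectin, by 7.86. The largest falls were the lens crystallins Crygd (-8.03), Crygb (-7.95) and Crygf (-7.64), whose Dscr1KO means of 3.2, 7.8 and 2.25 lie near the added constant of 3.6, so their sizes and order depend on it. They were followed by Crybb3 (-4.30), Cryba1 (-3.96) and Crygs (-3.78). The sex-linked genes Xist (8.27), Eif2s3y (-6.68), Kdm5d (-4.66) and Uty (-4.49) were also among the largest changes, as was Ang (-3.89), which encodes the ribonuclease angiogenin. Rcan1 differed by -0.67 ± 0.20 (adjusted p = 0.0663), which did not pass the threshold.

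By gene list, the changes in Dscr1KO covered keratinisation, conjunctiva, leukocytes and vessels. Of 12 conjunctiva and goblet cell genes, 5 rose (7 adjusted over the list alone, adjusted p = 0.258 with an estimated correlation). Of 9 corneal endothelial genes, 2 fell (5 adjusted over the list alone, adjusted p = 0.428 with an estimated correlation). Of 15 keratinisation genes, 11 rose (13 rises and 1 fall adjusted over the list alone), with Lor, the envelope protein loricrin, up by 6.90 and Sprr1b by 7.33 (camera adjusted p = 3.63e-10 at the preset correlation, adjusted p = 0.175 with an estimated correlation). Of 11 neutrophil genes, 10 rose in both counts, among them S100a9 by 5.61 and the receptor gene Csf3r by 4.57 (adjusted p = 0.0713 with an estimated correlation). Of 18 macrophage genes, 12 rose (15 adjusted over the list alone), with Mpeg1 up by 4.40 and Csf1r, the receptor for macrophage growth factor, by 3.77 (adjusted p = 0.258 with an estimated correlation). Of 20 blood endothelial genes, 16 rose (17 adjusted over the list alone), including the apelin receptor gene Aplnr by 6.29 and Vwf, von Willebrand factor, by 4.82. Of 8 lymphatic genes, 6 rose in both counts, including Thy1 by 4.37 and the hyaluronan receptor gene Lyve1 by 3.61. Both vessel lists had an adjusted p = 0.0713 with an estimated correlation. Of 19 inflammatory genes, 6 rose (12 adjusted over the list alone), with the neutrophil chemokine genes Cxcl5 up by 6.31 and Cxcl1 by 4.87 (adjusted p = 0.175 with an estimated correlation). In the lens list 10 of 14 genes fell (14 adjusted over the list alone, adjusted p = 0.258 with an estimated correlation).

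Genes of lipid handling were divided in Dscr1KO. None of 17 cholesterol synthesis genes passed the threshold, by either count, and the lowest p belonged to Tm7sf2, a sterol reductase gene (-0.56 ± 0.16, adjusted p = 0.0556), and Fdps (-0.66 ± 0.21, adjusted p = 0.0848). In the efflux and LXR list, 5 of 18 genes rose in both counts, among them Cyp7b1, an oxysterol hydroxylase gene, by 3.44 and Pltp, phospholipid transfer protein, by 2.61 (adjusted p = 0.403 with an estimated correlation). Fabp4, a fatty acid binding protein of fat cells and macrophages, rose by 4.49 within a lipid uptake list in which 5 of 11 genes rose in both counts (adjusted p = 0.384 with an estimated correlation). In all, 989 genes rose and 493 fell, 1482 together, against 3729 at an unadjusted p under 0.05. With only these 4 arrays fitted, 611 rose and 132 fell, so the share of falls depends on the fit. The count was 345 without WT replicate 1, 263 without WT replicate 2 and 3849 without Dscr1KO replicate 1. It was 743 when only these 4 arrays were fitted and 700 without both libraries of doubtful Apoe level.

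The double KO was compared with WT to see the effect of losing both genes. The same kinds of epithelial transcript led the rises: Rptn by 9.61 ± 0.36 (adjusted p = 2.34e-05), Krtdap by 9.57, Sprr1b by 9.25, Sprr2f by 9.14, Sprr3 by 8.92, Sprr2d by 8.81 and Dmkn by 8.58. The antimicrobial peptide genes Defb3 and Defb4 rose by 8.87 and 8.84, and Serpinb12, a protease inhibitor gene, by 8.64. Of the 10 largest falls, 9 were crystallins, led by Crygd (-8.41), Crygf (-7.34), Crygb (-7.17), Crygs (-6.64), Cryba1 (-6.34) and Cryaa (-5.86), with Cryba4 (-4.85), Crybb2 (-4.67) and Cryba2 (-4.48) after them. The other was Ppp1r3c, a glycogen-targeting subunit of a phosphatase, at -4.59 ± 0.95. Rcan1 fell by 0.84 ± 0.20 (adjusted p = 0.0217).

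In double KO, 13 of 15 keratinisation genes rose and 1 fell (adjusted p = 0.183 with an estimated correlation), and all 14 lens genes fell (adjusted p = 0.231 with an estimated correlation), the same numbers when adjusted over the list alone. Lipid genes moved both ways. Of 17 cholesterol synthesis genes, 4 fell, or 6 adjusted over the list alone: Sc5d by 0.96, Tm7sf2 by 0.94, Nsdhl by 0.93 and Sqle, squalene epoxidase, by 0.84 (camera adjusted p = 0.00227, adjusted p = 0.51 with an estimated correlation). In the SREBP list, 7 of 14 genes fell and 2 rose in both counts, with Elovl6, a fatty acid elongase, down by 1.52, Acss2 by 1.45 and the sterol sensor Insig1 by 1.22, while Me1, malic enzyme, rose by 3.18 (adjusted p = 0.45 with an estimated correlation). The lipid uptake genes Fabp4 (6.51), Lpl, lipoprotein lipase (4.39), the fatty acid transporter Cd36 (4.23) and the scavenger receptor Msr1 (2.66) rose, 6 of 11 in the list (8 adjusted over the list alone, adjusted p = 0.241 with an estimated correlation). Abca1, a cholesterol export pump, rose by 2.51, Cyp7b1 by 3.997, Nceh1, a cholesteryl ester hydrolase gene, by 2.38 and Pltp by 2.07 in an efflux and LXR list with 6 of 18 genes up and 1 down (7 and 2 adjusted over the list alone). Leukocyte and vessel genes rose as well: 10 of 11 neutrophil genes (11 adjusted over the list alone, adjusted p = 0.108 with an estimated correlation) and 13 of 18 macrophage genes (15 adjusted over the list alone, adjusted p = 0.241 with an estimated correlation), with Mpeg1 up by 4.92 and the complement gene C1qa by 4.29. Of 20 blood endothelial genes 16 rose (17 adjusted over the list alone, adjusted p = 0.115 with an estimated correlation), Vwf by 5.47, and of 8 lymphatic genes 6 rose in both counts, Lyve1 by 5.63 (adjusted p = 0.116 with an estimated correlation). Altogether 1430 genes rose and 1106 fell, 2536 of 12711, against 4376 at an unadjusted p under 0.05. The count was 931 without WT replicate 1, 691 without WT replicate 2 and 1565 without double KO replicate 1.

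Double KO against ApoeKO gives the effect of Dscr1 loss between groups that share the ApoeKO label. Rptn rose by 9.35 ± 0.36 (adjusted p = 1.83e-05), Krtdap by 9.28, Sprr1b by 9.24, Defb4 by 9.04, Serpinb3a by 8.78, Sprr3 by 8.59, Defb3 by 8.58, Sprr2d by 8.54, Sprr2f by 8.25 and Serpinb12 by 8.23. The largest falls were Ppp1r3c (-4.57 ± 0.95), Frem2, a basement membrane protein gene (-3.62), Pm20d1 (-3.58), Csn3, a casein gene (-3.40), Rasef (-3.21), Fxyd4 (-3.20), Med12l (-3.20), Klra8 (-3.12), the transporter gene Slc16a12 (-3.11) and the gastrokine gene Gkn1 (-2.96). Lens genes differed less here, since both groups had low crystallins: 2 of 14 fell in both counts, Crygd by 2.41 and Bfsp2, a lens filament gene, by 1.61 (adjusted p = 0.544 with an estimated correlation). Rcan1 fell by 0.81 ± 0.20 (adjusted p = 0.0272).

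Within this comparison, 6 of 17 cholesterol synthesis genes fell, or 10 adjusted over the list alone, among them Nsdhl by 1.27, Sc5d by 1.15, Tm7sf2 by 1.14 and Sqle by 0.95 (camera adjusted p = 6.18e-05, adjusted p = 0.408 with an estimated correlation). In the SREBP list 8 of 14 genes fell and 2 rose, or 10 and 2 adjusted over the list alone. Acss2 fell by 2.02, Insig1 by 1.61 and the desaturase gene Scd2 by 1.32 (adjusted p = 0.386 with an estimated correlation). Neutrophil genes rose in 10 of 11 cases (11 adjusted over the list alone, adjusted p = 0.126 with an estimated correlation), S100a8 by 7.02. Blood endothelial genes rose in 16 of 20 cases in both counts (adjusted p = 0.13 with an estimated correlation), with Vwf up by 6.16 and Plvap by 5.51. Matrix genes rose in 15 of 24 cases and fell in 1 (16 and 1 adjusted over the list alone, adjusted p = 0.273 with an estimated correlation), with Mmp13 up by 5.40 and the matrix protein gene Postn by 4.59. Of 19 corneal epithelial genes 6 fell and 2 rose (8 and 2 adjusted over the list alone), Pax6 falling by 1.34 (camera adjusted p = 0.0176, adjusted p = 0.408 with an estimated correlation). In the interferon list 2 of 17 fell in both counts, Ifit1 by 1.98 and Irf7 by 1.38 (adjusted p = 0.699 with an estimated correlation). Keratinisation genes rose in 13 of 15 cases, with 0 falls, or 13 and 1 adjusted over the list alone (adjusted p = 0.268 with an estimated correlation). Double KO replicate 1 also carried photoreceptor transcripts. The mean of the photoreceptor list on that array was 4.23 above the WT mean, against -1.24 in double KO replicate 2. Of 12711 genes, 1383 rose and 1093 fell, 2476 together, with 4382 at an unadjusted p under 0.05. The count was 793 without ApoeKO replicate 1, 516 without ApoeKO replicate 2 and 1322 without double KO replicate 1.

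**Figure D2:**
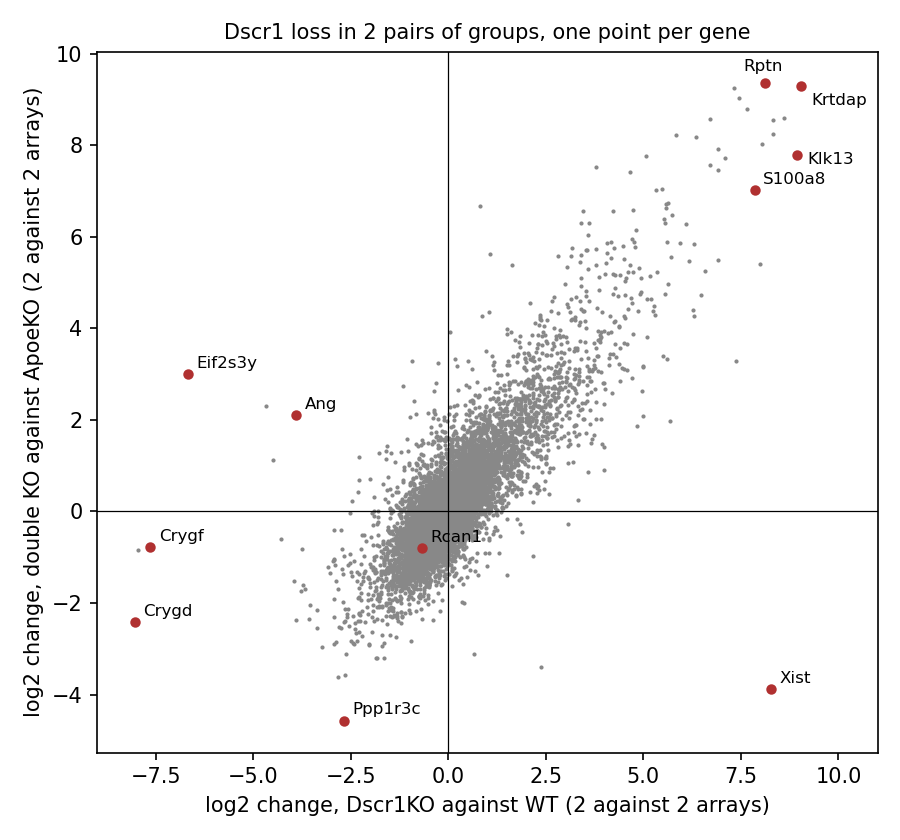
Log2 change of each of 12711 genes in Dscr1KO against WT (horizontal axis) and in double KO against ApoeKO (vertical axis), 1 point per gene. Krtdap, Rptn, Klk13 and S100a8 lie high on both axes, whereas Crygf, Xist, Eif2s3y and Ang differ between the axes.

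These contrasts share no array, and their log2 changes had a Pearson r of 0.817 and a Spearman rho of 0.706 across genes, which are not independent replicates. Of the genes that passed in both, 786 rose in both, against 107.6 from independent lists of these sizes, and 280 fell in both, against 42.4. Both sets of calls take each gene's spread from the same fit of all 8 intact arrays, so a gene of low spread passes more easily in both. The numbers for independent lists are therefore no chance level for this overlap. Of the 1069 genes called in both, 3 went opposite ways.

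Averaged over both Apoe groups, Dscr1 loss was compared in 4 against 4 intact corneas. Krtdap rose by 9.16 ± 0.48 (adjusted p = 3.58e-05) and Rptn by 8.73 ± 0.26 (adjusted p = 2.71e-06). Further rises were Sprr3 (8.60), Sprr2d (8.42), Klk13 (8.36), Sprr2f (8.29), Sprr1b (8.29), Defb4 (8.24), Serpinb3a (8.22) and Dmkn (8.04). Among genes whose groups do not overlap, falls were led by Crygd (-5.22 ± 0.43) and Crygf (-4.21 ± 0.27). Crygb, whose groups overlap, fell by 4.39 ± 0.44. The next were Ppp1r3c (-3.63), Frem2 (-3.23), the claudin gene Cldn10 (-3.13), Pm20d1 (-3.12), Gkn1 (-3.10), the calcium-binding protein gene Necab1 (-2.96), Enpep, an aminopeptidase that cleaves angiotensin (-2.96), and Npy, neuropeptide Y (-2.91). The lens list was also low in ApoeKO (-2.98 and -4.55 from the WT mean) and in sutured WT at day 5 (-3.89). The crystallin falls are therefore not particular to Dscr1 loss, and that of Crygf differed between Apoe labels by 6.86. Rcan1 fell by 0.74 ± 0.14 (adjusted p = 0.00634). A total of 2059 genes rose and 1944 fell, 4003 of 12711, with 5523 at an unadjusted p under 0.05. The count was 2412 without WT replicate 1, 2150 without WT replicate 2, 2448 without ApoeKO replicate 1, 2248 without ApoeKO replicate 2 and 2580 without both libraries of doubtful Apoe level. Among the 5 intact arrays with Xist it was 671, of which 669 were among the 4003. These 5 arrays include no WT and also entered the fit that gave the 4003, so the overlap is not independent.

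Keratinisation, conjunctiva, leukocyte and vessel lists moved up together in this average, while the corneal epithelial list did not (median -0.18). All 15 keratinisation genes but 1 passed the threshold, 13 rising and 1 falling in both counts, with Lor up by 7.18 ± 0.12 (camera adjusted p = 8.35e-09, adjusted p = 0.22 with an estimated correlation). Of 12 conjunctiva and goblet cell genes, 7 rose (8 adjusted over the list alone), including the mucin gene Muc5ac by 4.98 and the mucosal keratin gene Krt4 by 4.92 (adjusted p = 0.267 with an estimated correlation). All 11 neutrophil genes rose in both counts, S100a9 by 5.75 among them (adjusted p = 0.11 with an estimated correlation), and 14 of 18 macrophage genes rose (16 adjusted over the list alone), with Tyrobp up by 3.83 and Csf1r by 3.08 (adjusted p = 0.278 with an estimated correlation). Of 20 blood endothelial genes 17 rose, and of 8 lymphatic genes 6 rose, in both counts. Vwf was up by 5.49, Aplnr by 5.28, Lyve1 by 4.96 and Thy1 by 4.20 (adjusted p = 0.116 with an estimated correlation for either list). Of 24 matrix genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), including Mmp13 by 6.69, the collagen gene Col3a1 by 4.82 and tenascin, Tnc, by 4.80 (adjusted p = 0.278 with an estimated correlation). Cxcl5 rose by 6.07 and Cxcl1 by 4.62 in an inflammatory list with 13 of 19 genes up (15 adjusted over the list alone, adjusted p = 0.22 with an estimated correlation).

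Some cholesterol synthesis genes fell in this average. Of 17, 7 fell in both counts, including Tm7sf2 by 0.85, Sc5d by 0.83, Nsdhl by 0.77, Fdps by 0.75 and Sqle by 0.68, and the list median was -0.40 (camera adjusted p = 0.0021, adjusted p = 0.432 with an estimated correlation). The list level was -0.31 and -0.02 in Dscr1KO and -0.72 and -0.29 in double KO, against 0.09 and -0.09 in WT and 0.19 and 0.21 in ApoeKO. The higher ApoeKO level adds to the difference, and Dscr1KO replicate 2 lay within the WT range. In the SREBP list, 10 of 14 genes fell and 2 rose in both counts: Acss2 fell by 1.27, Insig1 by 1.17 and Elovl6 by 1.09, while Me1 rose by 2.92 (adjusted p = 0.432 with an estimated correlation). The efflux and LXR list split, with 6 of 18 genes up and 3 down (7 and 3 adjusted over the list alone), Cyp7b1 rising by 3.15 and Abca1 by 1.69. Lipid uptake genes rose in 7 of 11 cases and fell in 1, in both counts, with Fabp4 up by 5.14 and Lpl by 2.73 (adjusted p = 0.316 with an estimated correlation). Antioxidant genes rose in 7 of 17 cases in both counts, led by the glutathione peroxidase genes Gpx3 (5.83) and Gpx2 (5.40), with an adjusted p = 0.22 with an estimated correlation.

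Markers of the cornea's own layers and of the lens were lower or mixed. In the corneal epithelial list 6 of 19 genes fell and 2 rose (6 and 3 adjusted over the list alone), with the eye transcription factor gene Pax6 at -1.18 and the basal keratin gene Krt14 at 2.11, and camera did not call the list (adjusted p = 0.231). Corneal endothelial genes fell in 6 of 9 cases (7 adjusted over the list alone), including Col8a1 by 2.08 and the transporter gene Slc4a11 by 1.47 (adjusted p = 0.432 with an estimated correlation). Kera, the proteoglycan keratocan, fell by 2.06 within a keratocyte list that held 5 rises and 5 falls among 17 genes in both counts. Its median was -0.09 while the camera direction was up, with no call (adjusted p = 0.945). Lens genes fell in 12 of 14 cases (14 adjusted over the list alone, adjusted p = 0.338 with an estimated correlation), and among the 5 intact arrays with Xist the lens median was 0.02 with no member called. The arrays with Dscr1 among these are the ApoeKO libraries, whose lens list was already low (-2.98 and -4.55 from the WT mean). The median of 0.02 therefore does not tell whether the lens fall goes with sex. In the calcineurin and NFAT list, the genes Nfatc2 (-1.12) and Ppp3ca (-0.58) fell and Nfatc1 (0.64) rose among 13 genes, 2 falls and 0 rises adjusted over the list alone. Its median was 0.05 and its camera direction down, without a call (adjusted p = 0.945). NFAT-inducible genes rose in 9 of 15 cases and fell in 1 (10 and 1 adjusted over the list alone), with the adhesion genes Selp up by 4.53 and Icam1 by 2.97 (adjusted p = 0.165 with an estimated correlation).

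**Figure D3:**
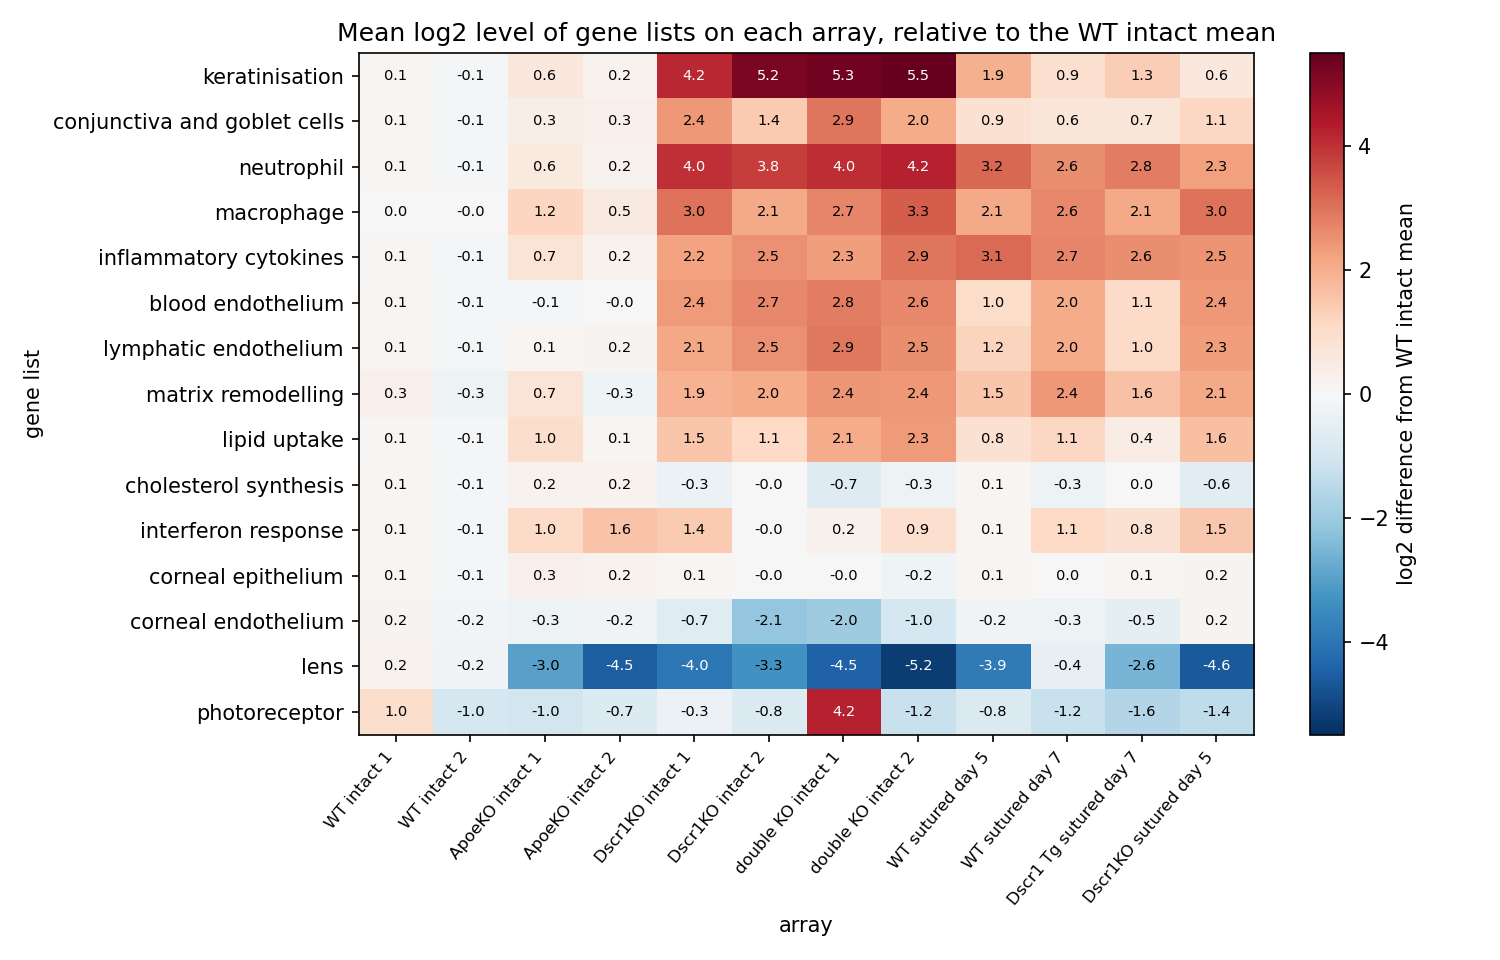
Mean log2 level of 15 gene lists on each of the 12 arrays, relative to the mean of the 2 WT intact arrays (colour and printed number). Cholesterol synthesis is at -0.31 and -0.02 in Dscr1KO and at -0.72 and -0.29 in double KO, and the lens list lies at -2.98 or lower on every intact array outside WT.

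ApoeKO was compared with WT to show what the ApoeKO label changes. Only 3 genes passed, all lens crystallins: Crygf fell by 6.57 ± 0.38 (adjusted p = 0.00201), Crygb by 6.33 ± 0.63 and Crygd by 6.00 ± 0.61 (both adjusted p = 0.047). At an unadjusted p under 0.05 there were 477 genes. The fit shares its spread over all intact groups, whose replicates differed unequally. At 2-fold, 214 genes differed between replicates in WT and 377 in ApoeKO, against 1638 in Dscr1KO and 1139 in double KO. A count of 3 therefore does not show that few genes differ with this label. The next lowest p were Il33, an alarmin cytokine (2.01 ± 0.23, adjusted p = 0.0862), and Casp1, an inflammasome protease (3.14 ± 0.40, adjusted p = 0.109). Apoe itself differed by -3.21 ± 1.68 (adjusted p = 1), since its transcript was present in the library labelled ApoeKO replicate 1. Of 14 lens genes 2 fell (13 adjusted over the list alone), with a list median of -3.69 (adjusted p = 0.377 with an estimated correlation). From the intact WT mean, the lens list also lay at -3.96 and -3.33 in Dscr1KO. In sutured WT it was at -3.89 on day 5 and -0.44 on day 7. The crystallin falls are therefore not particular to the ApoeKO label, and their cause was not tested. The interferon list had a median of 0.94 with 0 of 17 genes called (5 adjusted over the list alone), Usp18 reading 2.33 higher (adjusted p = 0.522 with an estimated correlation). The cholesterol synthesis list had a median of 0.20 with 0 of 17 called in both counts (camera adjusted p = 0.00855, adjusted p = 0.701 with an estimated correlation). The count of 3 became 0 without WT replicate 1, 1 without WT replicate 2, 1 without ApoeKO replicate 2, 6 without ApoeKO replicate 1 and 203 when these 4 arrays alone were fitted. It was 9 without both libraries of doubtful Apoe level, and 0 at the stricter filter.

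Double KO against Dscr1KO gives the effect of the Apoe label without Dscr1. The 3 genes that passed lie on chromosome 14 and were all higher in double KO. Ang rose by 6.53 ± 0.45 (adjusted p = 0.00737), Rnase2b, an eosinophil-type ribonuclease gene, by 4.53 ± 0.35 (adjusted p = 0.00957) and Pnp, purine nucleoside phosphorylase, by 1.62 ± 0.16 (adjusted p = 0.0421). At an unadjusted p under 0.05 there were 1363 genes. Selenbp1 (1.62 ± 0.20) and Serpinb12 (2.80 ± 0.36) followed, both at adjusted p = 0.15. Apoe differed by -4.38 ± 1.68 (adjusted p = 0.458). The shared spread of the fit includes WT and ApoeKO, whose replicates differed at 2-fold in 214 and 377 genes. Replicates of Dscr1KO and double KO differed in 1638 and 1139. In the cholesterol synthesis list 0 of 17 genes were called in both counts, with a median of -0.38 (camera adjusted p = 0.00282, adjusted p = 0.712 with an estimated correlation). The count was 107 without Dscr1KO replicate 1, 96 without Dscr1KO replicate 2, 54 without double KO replicate 2, 21 without both libraries of doubtful Apoe level, and 0 when these 4 arrays alone were fitted.

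Averaged over both Dscr1 groups, the Apoe label gave 1 rise and 1 fall, Ang by 3.53 ± 0.32 and Crygf by -3.13 ± 0.27 (both adjusted p = 0.0276), with 757 genes at an unadjusted p under 0.05. Pnp (1.08 ± 0.11, adjusted p = 0.0648), Rnase2b (2.25 ± 0.25, adjusted p = 0.0649) and Cryaa (-3.67 ± 0.45, adjusted p = 0.103) came next. Neither called gene changed alike in both Dscr1 groups. Ang differed by 6.53 in double KO against Dscr1KO, but read 182.5 and 135.5 in ApoeKO and 114.5 and 101.5 in intact WT. The change of Crygf differed between Dscr1 groups by 6.86. Across genes, the Apoe label changes with and without Dscr1 had a Pearson r of -0.015 and a Spearman rho of -0.081. Macrophage genes had a median of 0.76 with 0 of 18 called (6 adjusted over the list alone, adjusted p = 0.571 with an estimated correlation), and the mannose receptor gene Mrc1 read 1.03 ± 0.19 higher (adjusted p = 0.326). The count was 0 without WT replicate 1, WT replicate 2 or ApoeKO replicate 2. It was 6 without ApoeKO replicate 1, 20 without Dscr1KO replicate 1, 47 without Dscr1KO replicate 2 and 12 without double KO replicate 2. Quantile normalization gave 3 rises and 1 fall. Without both libraries of doubtful Apoe level 2 genes fell and 0 rose, with neither Ang nor Crygf among them, and with a term for Xist neither was called.

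The interaction asked whether Dscr1 loss acts differently with the Apoe label, and Crygf alone passed, at 6.86 ± 0.54 (adjusted p = 0.0199). The lens gene was at 1204 ± 451 (SD, n = 2) in WT and at 9.15 ± 4.74 in ApoeKO, so its fall with Dscr1 loss was open only from WT. Ang (6.00 ± 0.63) and Rnase2b (4.56 ± 0.50), both at adjusted p = 0.0782, and Cpxm1 (2.36 ± 0.28) and Crygb (7.11 ± 0.89), both at adjusted p = 0.0985, had the next lowest p. At an unadjusted p under 0.05 there were 964 genes. In the cholesterol synthesis list 0 of 17 genes were called in both counts, with a median of -0.58 (camera adjusted p = 4.71e-05, adjusted p = 0.706 with an estimated correlation), Nsdhl reading -1.01 ± 0.27. The count was 0 without any 1 of the WT or ApoeKO arrays, 19 without Dscr1KO replicate 1, 50 without Dscr1KO replicate 2, 6 without double KO replicate 1 and 15 without double KO replicate 2.

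Suturing, which injures the cornea, was compared with the intact state in 3 sutured against 4 intact arrays, with Dscr1 genotype as a term. No gene passed in limma, and 1251 had an unadjusted p under 0.05. The lowest p belonged to Cemip, a hyaluronan-binding protein gene (1.51 ± 0.21), the integrin gene Itgb1 (0.92 ± 0.13), Il1f5 (-1.68 ± 0.24), Id3 (1.46 ± 0.21) and the matrix-associated gene Ccn2 (1.84 ± 0.27), all at adjusted p = 0.348. Macrophage genes had a median of 1.72 with 0 of 18 called (13 adjusted over the list alone, adjusted p = 0.444 with an estimated correlation). Cholesterol synthesis genes had a median of -0.23 with 0 of 17 called in both counts (camera adjusted p = 0.0146, adjusted p = 0.522 with an estimated correlation). The count was 134 without the sutured Dscr1KO array and 1 without Dscr1KO intact replicate 1.

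Among the WT arrays alone, 2 sutured against 2 intact with days 5 and 7 pooled, 411 genes rose and 172 fell. These were 583 together, with 2955 at an unadjusted p under 0.05. When the intact Dscr1KO arrays were kept in the fit, 132 rose and 2 fell, so the falls in particular depend on the fit. Saa3, an acute-phase protein gene, rose by 8.84 ± 0.41 (adjusted p = 0.00094), Ppbp, a platelet chemokine gene, by 7.10, S100a8 by 6.45, the matrix proteases Mmp3 and Mmp12 by 6.44 and 5.55, the chemokines Cxcl2 and Cxcl5 by 6.33 and 6.05, Chil1 by 6.22, Srgn by 5.63 and the injury keratin gene Krt16 by 5.55. Gng13 fell by 2.63 ± 0.30 and Necab1 by 2.58 ± 0.19. Syt7 (-2.14), Gm20383 (-2.06), Ly6g6c (-2.05), Upk3b (-2.00), Acsm2 (-1.95), 2610206C17Rik (-1.85), Tfap2e (-1.82) and Gldc (-1.81) followed. Macrophage genes rose in 13 of 18 cases (17 adjusted over the list alone, adjusted p = 0.553 with an estimated correlation). Inflammatory genes rose in 11 of 19 cases (17 adjusted over the list alone) and neutrophil genes in 6 of 11 (9 adjusted over the list alone), both with an adjusted p = 0.406 with an estimated correlation. Cholesterol synthesis genes were not called in any of 17 cases in either count (camera adjusted p = 0.667).

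The sutured genotypes were compared with 1 array each, so the differences have no replicate check and no test. Genes of a list can move together, so its percentile among random lists is a description and not a measure of support. Replicates of a genotype can differ on a list as well. The intact Dscr1KO replicates lay 0.31 and 1.52 above the intact WT mean on the immediate early and dissection-stress list. At day 5, 524 genes were at least 2-fold higher and 247 lower in Dscr1KO than in WT. Lpl was 3.21 higher on the log2 scale (478 against 48.3), Ttr, a thyroid hormone and retinol carrier, 3.20, Wfdc18 2.92, Cd36 2.63, Col3a1 2.63, the interferon-induced genes Rsad2 2.59 and Ifi27l2a 2.30, Ctla2a 2.36, the endothelial gene Clec14a 2.35 and the smooth muscle gene Tagln 2.30. Lower were Sprr2d (-6.84), the acute-phase genes Saa1 (-6.00) and Saa2 (-4.94), Sprr2f (-5.35), Sprr2h (-4.77), S100a9 (-3.98), Mab21l3 (-3.47), Sprr1b (-3.44), B3galt5 (-3.41) and the natriuretic peptide gene Nppb (-3.33). All 17 cholesterol synthesis genes were lower, with a median of -0.81 at percentile 0 of 10000 random lists matched in expression, among them Mvd (-1.13), Lss (-1.13) and Cyp51 (-1.11). All 20 blood endothelial genes were higher, with a median of 1.49 at percentile 100, and so were all 17 interferon genes, with a median of 1.23. Pigment cell and iris genes were higher in 11 of 11 cases (median 1.33), Tyrp1 by 1.97. Keratinisation genes were lower in 12 of 15 cases (median -1.02). On the lists above, the WT array of day 5, the reference here, stands apart from WT at day 7 in the same directions. Other lists went opposite ways. Lens genes had a median of -0.85 here and 3.20 for day 7 against day 5, and immediate early genes 0.20 and -1.16. Day 7 against day 5 had medians of -0.47 for cholesterol synthesis (15 of 17 lower), 1.01 for blood endothelial genes (20 of 20 higher), 0.85 for interferon genes (16 of 17 higher) and -0.67 for keratinisation (10 of 15 lower). These differences can therefore not be assigned to Dscr1 from 1 array each.

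At day 7, 96 genes were at least 2-fold higher and 442 lower in Tg than in WT. Higher were Saa2 (3.77), Saa1 (3.58), the cornified-cell gene Cnfn (3.08), Sprr2h (2.42), S100a9 (2.25), Klra8 (2.08), the iron-binding protein gene Lcn2 (1.94), Slco1a5 (1.88), and the immediate early genes Fosb (1.85) and Atf3 (1.82). Lower were G530011O06Rik (-4.61), the crystallins Cryaa (-3.58), Crygf (-3.38), Cryba1 (-2.84), Crybb2 (-2.48) and Cryba2 (-2.48), Csn3 (-2.88), Wfdc18 (-2.65), the small proteoglycan gene Aspn (-2.54) and Penk (-2.45). Rcan1 differed by -0.08 on the probe set used, so a raised Rcan1 was not seen there, and whether its probes match the transgene is not given in the sources used here. Blood endothelial genes were lower in 19 of 20 cases (median -1.03, percentile 0), matrix genes in 22 of 24 (median -0.72) and lens genes in 14 of 14 (median -2.38). Keratocyte genes were lower in 16 of 17 cases (median -0.76, percentile 0), pigment cell and iris genes in 10 of 11 (median -0.79, percentile 0.02) and macrophage genes in 16 of 18 (median -0.59), and immediate early and dissection-stress genes were higher in 16 of 19 (median 0.38, percentile 100). On the blood endothelial, matrix and lens lists the WT array of day 7 differed from that of day 5, with medians of 1.01, 0.87 and 3.20, about as much as Tg from WT or more. Cholesterol synthesis genes were higher in 15 of 17 cases, with a median of 0.31 at percentile 100. The WT array of day 7, the reference here, was itself lower than the WT array of day 5 on this list, in 15 of 17 cases with a median of -0.47 at percentile 0, a larger difference than that of Tg. The differences of Dscr1KO at day 5 and of Tg at day 7, each from its own WT array, had a Pearson r of -0.441 and a Spearman rho of -0.434 across genes. These WT arrays differ from each other, as on the blood endothelial list (1.01), and that difference alone could give a negative r. The r therefore does not show opposite effects of Dscr1 loss and gain. The differences of Dscr1KO from WT at day 5 and in the intact cornea had an r of 0.049 and a rho of 0.012.

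Between days 5 and 7 in sutured WT, 416 genes were at least 2-fold higher and 254 lower at day 7. Lens genes led the higher side, with Crygb 6.74, Crygd 6.31, Cryba1 4.33, Crygs 3.995, Cryaa 3.54, Cryba2 3.33 and Crybb2 3.07, next to G530011O06Rik (4.11), Csn3 (3.12) and the fibroblast gene Lrrc15 (2.96). Lower at day 7 were Saa2 (-4.87), Saa1 (-4.81), Sprr2h (-3.85), Nr4a3 (-3.49), Fosl1 (-3.15), S100a9 (-3.10), Klk13 (-3.03), Sprr2d (-3.01), Sbsn (-3.00) and Dmkn (-2.99). Immediate early and dissection-stress genes were lower in 19 of 19 cases (median -1.16, percentile 0), lens genes higher in 14 of 14 (median 3.20) and blood endothelial genes higher in 20 of 20 (median 1.01). For scale, replicate pairs of intact corneas differed by at least 2-fold in 214 genes in WT, 377 in ApoeKO, 1638 in Dscr1KO and 1139 in double KO.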

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

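A difference between groups drew attention to Crygf, a lens crystallin gene, whose change with Dscr1 loss differed between Apoe labels by 6.86 ± 0.54 on the log2 scale (limma adjusted p = 0.0199). The lens list as a whole also differed between sutured WT arrays, at -3.89 on day 5 and -0.44 on day 7 from the intact WT mean. The cause of these lens differences was not tested. A fit of suturing by genotype, in which sutured Dscr1KO is 1 array and its spread is taken from the other groups, called 76 genes as differing between genotypes, a difference with no replicate check (11 higher and 65 lower, against 1773 at an unadjusted p under 0.05). They include Sprr2d (-13.64 ± 1.56, adjusted p = 0.026), Sprr2f (-12.55), S100a8 (-9.65), Sprr3 (-9.34), Krtdap (-8.90), Xist (-8.65), Krt17 (-8.34), Mmp13 (-8.18), Cxcl5 (-7.89) and Rptn (-7.84). Eif2s3y (6.30), Kdm5d (4.75), Ang (4.69), Uty (4.58) and Tyrp1 (3.72) went the other way. Sex is confounded with suturing within Dscr1KO and the fit has no term for it: Xist read 4104 and 5385.2 in intact Dscr1KO, 6 in sutured Dscr1KO and 14.9 or less in every WT array. Krtdap read 1697.1 and 7451.7 in intact Dscr1KO and 2.4 in sutured Dscr1KO. The lone sutured Dscr1KO array is assumed to vary like the other groups, and the count was 2161 without Dscr1KO intact replicate 1, 289 without Dscr1KO intact replicate 2, 13 without WT intact replicate 1, 10 without WT intact replicate 2, 7 without WT at day 5 and 28 without WT at day 7.

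Of the tests on groupings of the arrays, those for the Dscr1 and Apoe averages were planned ahead and the one for suturing was chosen after its result was seen. For the Dscr1 average, 1 of 100 splits of the 8 intact arrays into groups of 2, the real one, gave as many as 4003 genes, and the highest other split, at 3684, kept the same arrays on each side of Dscr1. For the Apoe average, 4 of 100 splits gave as many as the real 2 genes, and the highest other split gave 3710, so most of the structure among the 8 arrays follows another division. For suturing, 34 of 34 splits of the 7 arrays gave at least the real count of 0, the highest other split giving 59. Any split must reach a count of 0, so these splits say nothing about suturing.

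The tests of the keratinisation rise in intact corneas without Dscr1 were chosen after the result was seen. If sex were the cause, the rise should vanish among the 5 arrays with Xist, where the list median was 4.75. The arrays with Dscr1 there are both labelled ApoeKO and none is WT, so the Apoe label is not balanced in this test. If carry-over of 1 neighbouring tissue of constant composition were the cause, its genes should keep a fixed ratio to each other. Their residual spread was 3.53 times that of corneal epithelial genes in the 4 arrays without Dscr1. The 13 genes were picked as called in these same arrays, and how much they vary within 1 tissue is not known here. The ratio therefore cannot exclude this carry-over. Carry-over of skin or conjunctiva in varying composition could dilute corneal genes. The corneal epithelial median was -0.18, with 6 of 19 genes falling and 2 rising, too small and mixed a shift to decide. Corneal endothelial genes had a median of -1.21, with 6 of 9 falling and 0 rising, and keratocyte genes held 5 rises and 5 falls among 17. Whether dilution lowered the corneal endothelial genes was not tested. A change of the corneal surface toward skin-type epithelium and carry-over, of constant or varying composition, remain possible. The sutured Dscr1KO array lay at only 0.57 on this list, against 4.16 to 5.49 in the 4 intact arrays without Dscr1. It also differs from intact Dscr1KO in suturing and in sex-linked transcripts. A cause other than Dscr1 loss that the 4 intact arrays share was not tested.

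The tests of Ang, Rnase2b and Pnp, which differ between double KO and Dscr1KO, were chosen after the result was seen. The 3 genes lie close together on chromosome 14, and 0 of 100000 random trios of tested genes lay on 1 chromosome within as short a span, an estimated share of 1e-05 when the real trio is counted as 1 more. This fits a different haplotype around these genes, which might come from the background of a line rather than from Apoe. Closeness alone cannot tell a haplotype from another local cause. Rnase4 (0.43, limma adjusted p = 0.576) and Rnase1 (1.36, adjusted p = 0.41) lie between Ang and Rnase2b and were not called. Cross-hybridisation among ribonuclease genes could not account for Pnp, a phosphorylase gene that differed by 1.62.

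The tests of the Apoe transcript were chosen after the result was seen. Apoc1 in the library labelled ApoeKO replicate 1 was at 0.912 of the WT mean, as an intact Apoe locus would give. A swap with the library labelled Dscr1KO replicate 2 could follow from its double label, but Apoc1 read 403.1 there, against 3.5 in the library labelled ApoeKO replicate 2. Whether the labelled library is a wild-type or heterozygous sample was not tested.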

How the results depend on the processing

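The alternatives changed counts more than directions. Over 1322 results for named genes there were 15315 alternative values, of which 14097 kept their call and direction, 952 were weaker, 190 stronger and 53 reversed, with 23 moved in size. Of the counts and summaries, 102 kept their call, 28 were stronger, 50 weaker and 13 moved in size. Quantile normalization moved the median change of all genes to between -0.075 and 0.05, and its counts were 1381 for Dscr1KO against WT, 2559 for double KO against WT, 2447 for double KO against ApoeKO and 4038 for the Dscr1 average. Signal near background limits the dim end: a gene near 3.6 or below in WT can show little of a fall, and the size of a rise from there, or of a fall that ends there, depends on the added constant. Where leaving out an array leaves 1 in its group, that lone sample is assumed to vary like the other groups. Except where fewer arrays or fewer genes tested are the alternative itself, the cause was not tested.

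The count for Dscr1KO against WT was 743 with only these groups, 700 without both doubtful libraries, and 263 to 3849 with 1 array left out. For ApoeKO against WT it was 0 with the strict filter, 1 with the smaller pseudocount, 1 without the trend, 203 with only these groups, 9 without both doubtful libraries and 0 to 6 with 1 array left out. Leaving out 1 array gave 691 to 2174 for double KO against WT and 516 to 2076 for double KO against ApoeKO. For double KO against Dscr1KO the count was 1 with the strict filter, 5 with the larger pseudocount, 0 with only these groups, 21 without both doubtful libraries and 4 to 107 with 1 array left out. The Dscr1 average gave 2580 without both doubtful libraries, 671 among the arrays with Xist, 3563 with a term for Xist, and 2150 to 5670 with 1 array left out.

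The Apoe average gave 1 with the strict filter, 4 under quantile normalization, 0 with the smaller pseudocount, 5 with the larger pseudocount, 0 without the trend, 1 with a term for Xist, 2 without both doubtful libraries, of which 0 were among the original 2, and 0 to 47 with 1 array left out. The interaction gave 2 with no filter, 0 with the strict filter, 4 with the larger pseudocount, 0 without both doubtful libraries and 0 to 50 with 1 array left out. Suturing gave 583 among WT arrays only, 134 as the wild-type coefficient of the fit by genotype, and 0 to 134 with 1 array left out, while its difference by genotype gave 7 to 2161. With an estimated correlation, 0 lists were called in each of the 9 comparisons.

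A replicate block, which pairs the samples by replicate number, gave 2 genes for the interaction, with 1253, 3, 2229, 2157, 2, 3667 and 2 for the 7 comparisons before it. The correlations of these pairs lay between -0.046 and 0.075, so the numbers do not pair the samples, and the block was not used.

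Single arrays without a test gave 1581, 1326 and 1461 genes at 2-fold without a filter, for Dscr1KO at day 5, Tg at day 7 and day 7 against day 5. They gave 410, 250 and 353 with the strict filter and 481, 289 and 423 with the larger pseudocount. With the strict filter the Pearson r was 0.833 for Dscr1 loss in the 2 Apoe groups, -0.017 for intact against sutured and -0.53 for Dscr1KO against Tg, and the last was -0.421 under quantile normalization.

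These values turned direction without both doubtful libraries: Apoe to 0.51 in Dscr1KO against WT, 1.47 in double KO against ApoeKO, 0.99 in the Dscr1 average and 0.97 in the interaction, Wfdc1 to -0.04 and Ifit2 to -0.12 in double KO against Dscr1KO, and H2-Ab1 to -0.36 in the Apoe average. Among the arrays with Xist, Apoe (1.33), Crygs (0.52) and Cryba1 (0.38) turned direction in the Dscr1 average. In suturing of WT arrays only, and as the wild-type coefficient, Rcan1 was -0.045, Lor 0.15, Krt10 0.018 and Tyrp1 -0.34. Under quantile normalization the camera direction turned, with no call before or after, for lists with these medians under it: the corneal epithelial list (-0.16, Dscr1KO against WT), the calcineurin list (-0.007 in ApoeKO against WT, -0.067 in double KO against Dscr1KO, 0.061 in the Dscr1 average and -0.06 in the interaction), the nerve list (0.021) and the oxidative stress list (0.016) in ApoeKO against WT, and the lymphocyte list (0.497) in the interaction. Among these lists the median itself changed sign only for the corneal epithelial and oxidative stress lists, and the cause was not tested. Single genes that turned under quantile normalization were Cd8a (0.039) and Uty (0.083) in Tg at day 7, and Mylpf (-0.01) and Cdh19 (-0.036) in day 7 against day 5.

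With 1 array left out, these ranges crossed 0. In Dscr1KO against WT they were Apoe (-1.49 to 0.51) and Sag (-2.38 to 0.041). In ApoeKO against WT they were Rcan1 (-0.138 to 0.062), Cd8a (-0.178 to 0.595) and Gnat1 (-3.84 to 0.674). Nrl ranged from -0.921 to 5.37 in double KO against WT, and Apoe from -4.79 to 1.47 in double KO against ApoeKO. In double KO against Dscr1KO they were Rcan1 (-0.425 to 0.078), Cd8a (-0.11 to 1.58), Wfdc1 (-0.039 to 0.826), Pde6g (-0.123 to 5.19), Irf7 (-0.886 to 0.1) and Ifit2 (-0.172 to 1.17). In the Dscr1 average they were Apoe (-2.64 to 0.491) and Rom1 (-0.042 to 1.8), and in the Apoe average Rcan1 (-0.231 to 0.02), H2-Ab1 (-0.304 to 0.818), Pde6g (-0.448 to 2.21) and Acta1 (-0.009 to 1.01). In the interaction they were Rcan1 (-0.387 to 0.116), Apoe (-4.3 to 1.96), Cd79b (-1.53 to 0.034) and Cd8a (-0.319 to 1.37). In suturing they were Rcan1 (-0.045 to 0.154), Lor (-3.64 to 0.151), Krt10 (-2.33 to 0.018), Tyrp1 (-0.343 to 1.597) and Gm20383 (-2.06 to 0.02).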

Other observations

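The chromosome 14 genes differed between the intact and the sutured Dscr1KO corneas. Pnp read 605.5 and 576.4 in intact Dscr1KO, 1617.9 and 2046.4 in double KO, 3333.6 in sutured Dscr1KO, and 2936.8 and 2648.7 in intact WT. Ang read 1.3 and 7.9 in intact Dscr1KO, 959.2 and 492.6 in double KO, 435.7 in sutured Dscr1KO, and 114.5 and 101.5 in intact WT. Rnase2b read 474 and 489.3 in double KO and 24.6 or less on every other array.

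Circadian clock genes fell in 6 of 14 cases in the average of Dscr1 loss in limma (1 rise and 9 falls adjusted over the list alone), with the clock output gene Dbp down by 1.30 (camera adjusted p = 0.0108, adjusted p = 0.278 with an estimated correlation). Antigen presentation genes rose in 5 of 8 cases (7 adjusted over the list alone, adjusted p = 0.432 with an estimated correlation). Complement genes rose in 6 of 9 cases and fell in 1, in both counts (adjusted p = 0.432 with an estimated correlation).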
